A study of Mus musculus with 5 samples.

How the data were processed

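RNA of C2C12 cells was measured on 5 Affymetrix arrays, with 1 array for each of 5 groups: parental cells and cells infected with GFP, wild-type MYOD1, MYOD1 L122R or MYC retrovirus. Per the labels' protocols, the cells grew in medium with fetal bovine serum, virus was made in 293T packaging cells, infected cells were selected with zeocin at 500 µg/ml for 1 week, and total RNA was extracted with Trizol and labelled with biotin. Groups were taken from the labels, and all 5 columns of the value table were matched to a sample by its labels.

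The deposited values are intensities on a linear scale, 1 per probe set, for 22690 probe sets. The submitters' processing notes name MAS5, with no version, role or settings. The values do not look like scaled and background-subtracted MAS5 signals: the smallest deposited intensity is 33, the array medians run from 108 to 141, which is a ratio of 1.31, the trimmed means are not set to a common target, and all but 52 probe sets hold whole numbers (tolerance 0). The plan fixed before the data were examined had assumed scaled values and was to use them as deposited. Quantile normalization, which that plan listed as an alternative, was therefore taken as the main setting, and the intensities as deposited became an alternative. The values appear to carry the chip background, in which case folds computed from them are smaller than the true ratios of transcript levels. Detection calls were not used here.

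The 64 control probe sets were set aside, and the other 22626 were quantile-normalized over the 5 arrays. Intensities under a floor of 89.6, the 40th percentile of all normalized values, were raised to the floor before log2 was taken. Gene names came from the platform's annotation, with symbols looked up by gene identifier in a table of the GRCm38.p6 assembly, which was used for names only. Of the probe sets, 20380 had 1 gene, 691 several and 1555 none, 20351 were found by identifier, and 0 symbols changed. The 12393 genes were each represented by the probe set with the highest mean log2 value over all arrays, probe sets with several genes were left out, and 3971 genes at the floor on all arrays were left out, which left 8422. The genome build and probe positions are not given in the sources used here, so no coordinates are printed.

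With 1 array per group there are 0 residual degrees of freedom, so no p-value or standard deviation was computed. A gene counted as higher or lower with a factor when it was at least 2-fold from both the GFP and the parental array in the same direction, and in a pair of arrays when they were at least 2-fold apart. Where 1 side lay at the floor the fold is a bound, written "at least". The numbers expected without change came from 100 simulations in which arrays were drawn around common levels with the differences seen between GFP and parental for genes of like signal, in 20 bins. Those differences hold any real difference between the controls, which raises the simulated counts. They do not hold culture or batch differences particular to the array of a factor, so the simulated counts can also be too small. For GFP against parental the simulation returns its own input and tests nothing.

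For gene lists, 25 lists with 726 entries were fixed before the data were examined, and 22 had at least 5 measured genes. The osteoblast, leukocyte and endothelial marker lists held 4, 4 and 3 measured genes and were not ranked. A list's median log2 fold change was placed among 10000 random lists of the same size matched on mean signal, and called when it lay in the outermost 2.5% on either side, against both controls for a factor. Genes at the floor entered at their bound. Percentiles describe these arrays and are not p-values.

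Genes are named by a rule fixed before the data were examined. It takes the 10 largest measured increases and decreases per comparison, the 5 largest bounds per direction, up to 4 members of each list past the rule of size, and always Myod1, Myc, Myog, Myf5, Myh3, Ckm, Acta1, Cdkn1a, Fgfr4, Odc1, Ncl, Cdk4, Cad, Gapdh and Actb. The text names fewer than the rule allows, and says where a gene outside it was named after its values were seen. Overlaps between factors are given beside the product of the list sizes over 8422 genes and beside simulated unchanged arrays that share the controls.

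The counting and list steps were tested on simulated data for wild-type MYOD1 against the controls, with 200 of 8422 genes changed in each of 20 runs. The changed genes were drawn only from bright genes, with a mean log2 signal more than 3 above the floor. The shares called below therefore do not cover dimmer genes. Of genes changed 3-fold, 87.0% were called in each direction, of those changed 4-fold 95.7% of increases and 96.5% of decreases, and of those changed 8-fold 100% and 99.1%, with a mean of 78.5 unchanged genes called. Lists of 30 random genes with a planted shift of log2 0.5 were called in 100 of 100 runs, and lists without one in 0 of 100. Noise was drawn separately for each gene. The test therefore gives no rate of false calls for lists whose genes vary together, and does not cover smaller shifts. Alternatives fixed before the data were examined were median scaling, floors at the 20th and 60th percentiles, no floor with the 40th percentile added before log2, the mean of all probe sets of a gene, leaving out probe sets that can cross-hybridise, each control alone, and a threshold per signal bin. The intensities as deposited and limma normexp background correction with offset 50 were added after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.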

Results

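Gene expression was measured in C2C12 cells, an established mouse myoblast line that can form muscle fibres in culture, on 5 one-colour Affymetrix arrays. One array (n = 1) came from each of 5 groups: parental cells, and cells infected with retrovirus carrying GFP, wild-type MYOD1, MYOD1 L122R or MYC and selected with zeocin at 500 µg/ml for 1 week. MYOD1 is a transcription factor that drives muscle differentiation, L122R replaces a leucine by an arginine in its DNA-binding basic region, and MYC is a growth-promoting transcription factor. The parental and GFP arrays served as the 2 controls. With 1 array per group there was no replicate error, no p-value was calculated, and the number of arrays limits the precision of every value below. Genes were therefore counted by size: at least 2-fold higher, or at least 2-fold lower, than both controls for an introduced factor, and at least 2-fold apart between arrays for a pair. A gene list was called higher or lower when its median log2 fold change lay beyond the outermost 2.5% of 10000 random lists of genes of similar signal on either side, against both controls for a factor. Because the values look as if background was not subtracted, folds are probably understated, most of all for dim genes.

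The median intensity of the 22690 probe sets lay between 108 on the wild-type MYOD1 array and 141 on the GFP array before normalization. Among the 8422 genes tested, the GFP array and the array labelled MYC were the most alike of the 10 pairs, with 26 genes 2-fold apart and a Spearman correlation across genes of 0.989. The parental and wild-type MYOD1 arrays followed, with 120 genes apart and a correlation of 0.976. The 2 controls differed from each other by 260 genes (0.954), and the wild-type MYOD1 array and the array labelled L122R differed most, by 529 genes (0.905). Genes are not independent replicates, so these correlations only describe the arrays. Probe sets for Actb, the beta-actin gene, read 14324 in parental, 13180 in GFP, 13477 in wild-type MYOD1, 15212 in L122R and 10827 on the array labelled MYC after normalization. Gapdh, a glycolytic enzyme gene, was not among the genes tested. Its control probe set at the 3' end had deposited intensities of 9257, 13891, 8772, 9362 and 12874 in the same order.

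The introduced genes were looked at before any comparison. The mouse Myod1 probe set read 471 in parental, 163 in GFP, 617 in wild-type MYOD1, 306 in L122R and 148 on the array labelled MYC. The mouse Myc probe set read 558, 1002, 497, 402 and 789 in that order, so it was 1.27-fold lower on the array labelled MYC than on the GFP array and 1.41-fold higher than on the parental array. The labels do not give the species of the introduced cDNAs, and these probe sets may report the endogenous mouse transcripts alone, in which case they check nothing. Because Myc was not higher than in GFP cells, that array is called the array labelled MYC. Likewise Myod1 on the array labelled L122R was 1.88-fold above GFP but 1.54-fold below parental. Myod1 on the wild-type MYOD1 array was 3.78-fold above GFP but only 1.31-fold above parental. Every direction drawn from any of these arrays rests on its label, and L122R standing alone below means the array so labelled.

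The GFP array was compared with the parental array to show how far the 2 controls differed, a difference that can hold infection, selection, culture and array effects. As groups, the lists of the amino acid and unfolded protein stress response and of glycolysis and hypoxia were called higher in GFP cells, and those of regulators that hold back myogenesis, of smooth muscle and of matrix were called lower, although most members of each list stayed within 2-fold. Ero1a, an endoplasmic reticulum oxidase, was 5.97-fold higher, and Cth, an enzyme of cysteine synthesis, was 4.45-fold higher. Id3, an inhibitor of MYOD1 family proteins, was 7.04-fold lower. In all, 127 genes were higher and 133 lower.

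Beyond these, Car6, a secreted carbonic anhydrase, was 21.9-fold higher in GFP than in parental cells, Dcn, the proteoglycan decorin, 15.3-fold and Tmem45a 6.79-fold. Scara5, a ferritin receptor, was 5.90-fold higher, Ccnd2, a G1 cyclin, 4.16-fold and Serpinb9b, a serpin, 4.09-fold. Avil, an actin-binding protein of the villin family, was at least 12.5-fold higher and Car9, a hypoxia-induced carbonic anhydrase, at least 3.79-fold. A Mycn probe set was at least 143-fold higher, rising from 78 to 12832, while the 2 other probe sets of that gene stayed at or below 69.4 on every array, under the floor of 89.6. The largest measured decreases were those of Islr (12.6-fold), Mest (9.28-fold), Car3 (8.18-fold), Id3, Cd200 (5.97-fold) and Inhbb (5.89-fold). Cxcr4, a chemokine receptor, was 5.59-fold lower and Nid2, a basement membrane protein, 5.14-fold lower.

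In the list of the unfolded protein and amino acid stress response, 10 of 27 measured genes were higher, 0 lower and 17 neither, and the median log2 fold change was 0.89. Psph, a serine synthesis enzyme, was 4.0-fold higher, Atf3, a stress-induced transcription factor, 3.52-fold, Trib3 2.79-fold and Asns, asparagine synthetase, 2.68-fold. The list of glycolysis and hypoxia had 11 of 29 genes higher, 0 lower and a median of 0.84, with Hk2, hexokinase 2, at 3.0-fold and P4ha2, a collagen prolyl hydroxylase, at 2.92-fold. The inhibitors of myogenesis had 6 of 20 genes lower and a median of -0.46, with Zeb1 2.56-fold, Id1 2.41-fold and Id2 2.35-fold lower. Of 33 extracellular matrix genes 7 were lower and 2 higher (median -0.35), with Ccn2 4.72-fold, Thbs1 4.16-fold and Col4a1 3.96-fold lower. Of 15 smooth muscle genes 5 were lower (median -0.40), among them Tagln (4.30-fold), Actg2 (2.80-fold), Myl9 (2.73-fold) and Acta2 (2.56-fold).

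The myogenic transcription factor list was also called lower in GFP cells (median -0.45), with 2 of 12 genes past 2-fold, Myod1 (2.88-fold) and Myog (2.26-fold). Sarcomere genes were called lower by a small median of -0.14, with 5 of 39 past 2-fold, including Myh7 (2.66-fold), Actc1 (2.62-fold) and Myh1 (2.58-fold). MYC targets in ribosome biogenesis were called higher with a median of 0.32 and 0 of 42 genes past 2-fold, and MYC targets in metabolism and growth were called higher with a median of 0.14 and 6 of 45 past it. The lists of S phase (-0.37), cell cycle exit (-0.35), muscle membrane (-0.24), MYC-repressed genes (-0.19), IGF, FGF and PI3K signalling (-0.13) and neural markers (-0.44, although Gap43, the only one of 6 past 2-fold, was 2.13-fold higher) were called lower, and the interferon list (0.18) higher. Without normalization between arrays, 285 genes were higher and 70 lower, because the GFP array was brighter, and Myog, Id1 and Id2 missed 2-fold. The calls of myogenic transcription factors, muscle membrane and neural markers were lost at a floor at the 20th percentile, and those of sarcomere, MYC-repressed and interferon genes at a floor at the 60th.

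**Figure D1:**
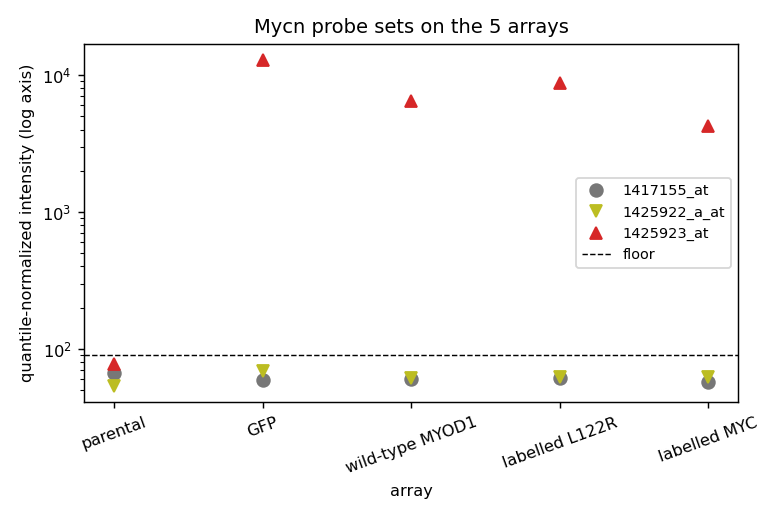
Quantile-normalized intensity of the 3 Mycn probe sets on the 5 arrays, on a log axis, with 1 point per array and the floor of 89.6 as a dashed line. One probe set reads 78.0 on the parental array and 12832 on the GFP array, and the other 2 stay at or below 69.4 on every array.

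The wild-type MYOD1 array was compared with both controls to ask how cells given this factor differed from them. Differences in culture density or differentiation state were not tested. A single array cannot separate them from an effect of the factor. Most genes of the contractile apparatus were higher. Actc1, cardiac alpha-actin, was 8.82-fold higher than in GFP and 3.36-fold higher than in parental cells, Mb, the oxygen store myoglobin, was 8.25-fold and 4.0-fold higher, and Myh3, embryonic myosin heavy chain, was 6.61-fold and 4.41-fold higher. Myog, the transcription factor myogenin, was 5.09-fold and 2.25-fold higher, and mitosis genes were lower as a group. The rule of size was met by 99 higher and 2 lower genes.

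Sarcomere and contraction genes had 31 of 39 measured members higher, 0 lower and 8 neither, with a median log2 fold change of 1.82 against GFP and 1.64 against parental. All 39 lay above 0 against each control. Examples in addition to Actc1 were Myh7 (8.28-fold above GFP and 3.11-fold above parental), the troponin Tnnt1 (7.30-fold and 3.56-fold) and the fast myosin heavy chain Myh1 (6.62-fold and 2.57-fold). Acta1, skeletal alpha-actin, was 3.50-fold and 3.40-fold higher, and Tnnt2, another troponin T, 5.97-fold and 3.56-fold. Genes of muscle calcium handling and energy had 11 of 24 members higher and 0 lower, with medians of 1.41 and 1.23. Ckm, muscle creatine kinase, was 5.74-fold and 4.57-fold higher, Ryr1, the calcium release channel, 3.95-fold and 3.57-fold, and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, 3.94-fold against each control.

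Of 12 myogenic transcription factors 2 were higher, Myog and Mef2c (3.80-fold and 3.27-fold), and the list was called higher with medians of 0.72 and 0.25. Myod1 itself was 3.78-fold above GFP but only 1.31-fold above parental cells. Muscle membrane, synapse and fusion genes were called higher (0.69 and 0.56), with 2 of 22 past the rule: Mymk, the fusion protein myomaker (3.56-fold and 3.84-fold), and Chrng, the fetal acetylcholine receptor subunit (3.46-fold and 2.89-fold). Genes outside the lists included C1qtnf3 (7.82-fold and 2.61-fold), Lrrn1 (6.82-fold and 2.59-fold) and Apobec2, a muscle-enriched deaminase family member (6.01-fold and 3.44-fold). Fst, the activin and myostatin antagonist follistatin, was at least 7.42-fold above GFP, where it lay at the floor, and 3.39-fold above parental. Pfkm, muscle phosphofructokinase, was 3.08-fold and 2.60-fold higher, the only one of 29 glycolysis and hypoxia genes past the rule.

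Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, was 2.75-fold above GFP and 2.14-fold above parental. It was the only one of 13 cell cycle exit genes past the rule, and that list was not called, with medians of 0.67 and 0.04. Mitosis genes had medians of -0.59 and -0.70, and 0 of 28 lay above 0 against either control, although only Kif2c, a microtubule depolymerase, passed the rule (2.12-fold and 2.07-fold lower). S phase genes were not called, since their median was -0.04 against GFP and -0.49 against parental. MYC targets in metabolism and growth were called lower (-0.29 and -0.14, 0 of 45 past the rule), and ribosome biogenesis genes were not called (-0.39 and -0.06). Extracellular matrix genes (0.33 and 0.08, 0 of 33) and MYC-repressed genes (0.18 and 0.07, 1 of 28) were called higher. Gsta4, a glutathione transferase, was the other lower gene, 2.37-fold below GFP and 2.45-fold below parental.

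Groups drawn with no change, with noise taken from the differences between the controls, gave on average 42.6 higher and 39.4 lower genes, and at most 57 and 53, so the 99 higher genes exceeded the simulated maximum and the 2 lower genes were fewer than the simulated mean. Against a single control the counts were 251 higher and 140 lower (GFP) or 110 and 10 (parental), with a threshold per signal bin 182 and 0, and without normalization between arrays 63 and 16, where Myog and Cdkn1a missed the rule; Cdkn1a also missed it with median scaling, and Kif2c under 4 other settings.

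**Figure D2:**
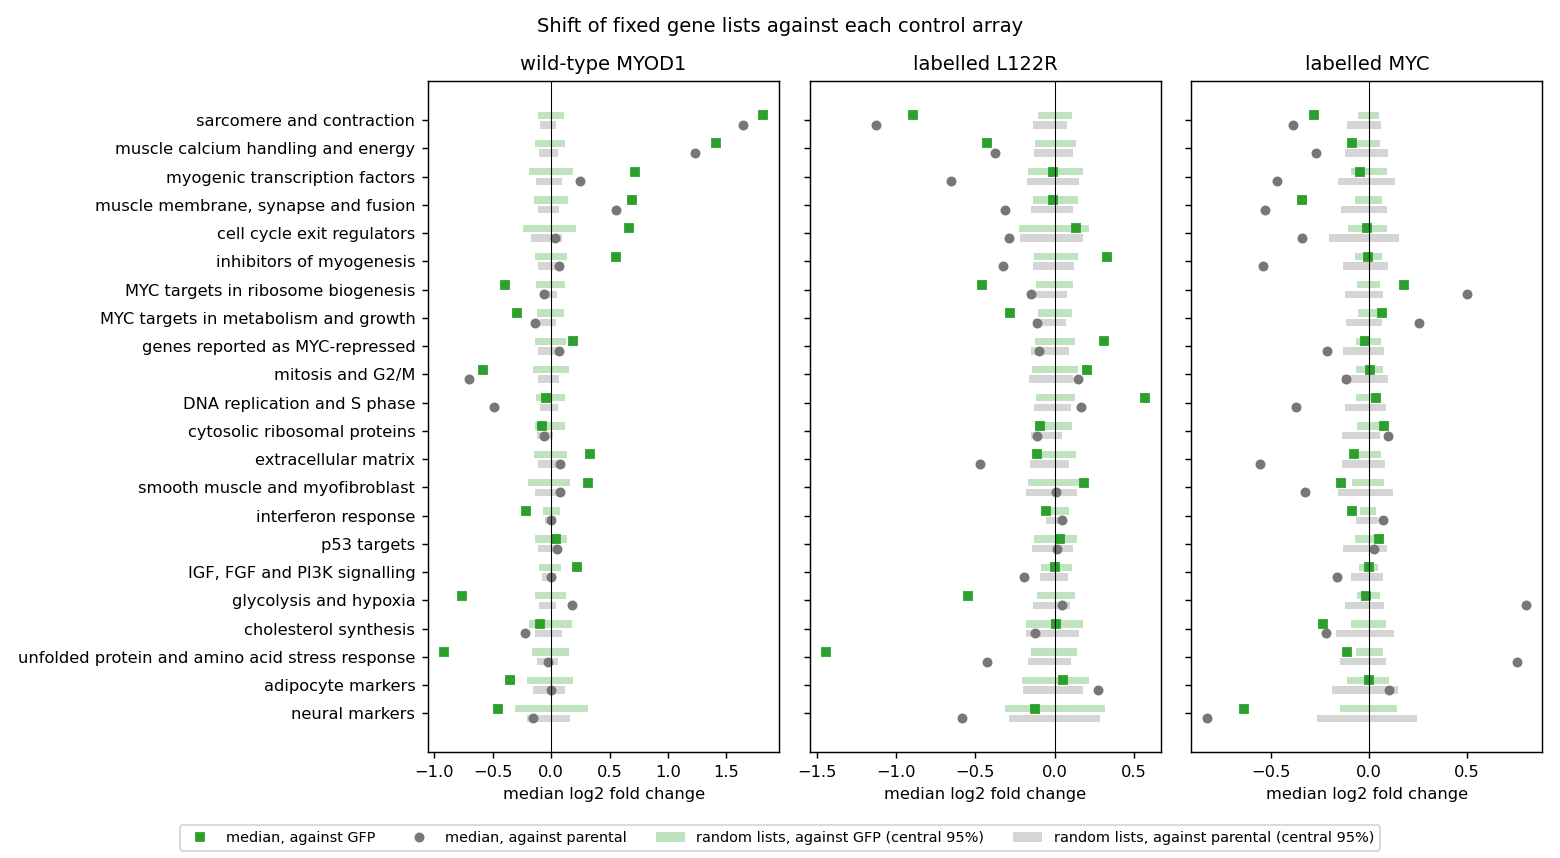
Median log2 fold change of 22 fixed gene lists on the wild-type MYOD1 array and the arrays labelled L122R and MYC, against the GFP array (green squares) and the parental array (grey circles), with shaded bars for the range of 10000 random lists without the outermost 2.5% on each side. Sarcomere genes lie at 1.82 and 1.64 for wild-type MYOD1 and at -0.89 and -1.13 for L122R, and ribosome biogenesis genes lie at 0.18 and 0.50 for the array labelled MYC.

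The array labelled L122R was compared with both controls to ask how cells given the substituted factor differed from them. Sarcomere genes were lower as a group, and 16 of 39 were at least 2-fold below both controls. Myl1 and Mylpf, fast muscle myosin light chains, were 28.0-fold and 27.5-fold below GFP and 28.0-fold and 26.8-fold below parental, and Myog was at least 9.56-fold and 21.6-fold lower. The matrix list was not called, but its member Postn, periostin, was at least 80.2-fold above GFP and 21.2-fold above parental. DNA replication genes were modestly higher and stress response genes lower as groups. The rule was met by 120 higher and 83 lower genes.

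Sarcomere and contraction genes had 16 of 39 members lower, 0 higher and 23 neither, with medians of -0.89 against GFP and -1.13 against parental. Acta1 was 12.6-fold and 13.0-fold lower, Tnni2, fast troponin I, 10.1-fold and 7.21-fold, and Actc1 7.67-fold and 20.1-fold. Myl4 was at least 17.7-fold and 14.7-fold lower, Myh3 at least 16.2-fold and 24.2-fold, Mybph at least 15.7-fold and 14.5-fold and Tnni1 at least 15.6-fold and 18.8-fold, all with the array labelled L122R at the floor. Calcium handling and energy genes were called lower (-0.42 and -0.38), with 4 of 24 lower and 1 higher. Casq2, calsequestrin, was 7.63-fold and 6.08-fold lower, Mb 3.0-fold and 6.18-fold and Ckm 2.35-fold and 2.94-fold, while Ckb, the brain-type creatine kinase, was 5.71-fold and 3.01-fold higher. The call of this list was lost at a floor at the 60th percentile.

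Not every muscle gene was lower. Mymk was 2.96-fold above GFP and 3.18-fold above parental, and Sgca, a sarcoglycan of the muscle membrane, 3.57-fold and 2.82-fold, while Chrng (at least 2.93-fold and 3.51-fold) and Ncam1 (2.81-fold and 3.09-fold) were lower. The muscle membrane list, with 2 of 22 higher and 2 lower, was not called (-0.01 and -0.31), nor were the myogenic transcription factors (-0.01 and -0.65), where Myog alone of 12 passed the rule. Id2, an inhibitor of MYOD1 family proteins, was 7.47-fold and 3.17-fold higher, and Msc, the bHLH repressor musculin, 2.40-fold and 2.48-fold. The list of inhibitors of myogenesis lay on opposite sides of the controls, at 0.33 against GFP and -0.32 against parental.

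Among secreted and matrix genes, Ccn2 was 23.6-fold above GFP and 4.99-fold above parental, Ccn3, of the same family, 19.2-fold and 37.1-fold, and Thbs2, thrombospondin 2, 15.4-fold and 21.0-fold. Timp3, a metalloproteinase inhibitor, was 9.81-fold and 5.86-fold lower and Bgn, the proteoglycan biglycan, 9.80-fold and 15.3-fold lower. Of 33 matrix genes 4 were higher and 6 lower, and the list was not called (-0.11 and -0.47). Other higher genes were Slpi, a secreted protease inhibitor (14.3-fold and 22.3-fold), Igsf5 (9.13-fold and 7.25-fold), Dtx1, a regulator of Notch signalling (8.72-fold and 8.62-fold), Stc2 (8.42-fold and 10.9-fold) and Apcdd1, a WNT inhibitor (8.13-fold and 12.8-fold). Plagl1, a zinc finger transcription factor, was at least 16.4-fold and measured 15.0-fold higher, and Myo7a, an unconventional myosin, at least 9.25-fold against each control.

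S phase genes were called higher, with medians of 0.57 and 0.17. All 30 lay above 0 against GFP and 25 against parental, and 2 passed the rule, Rrm2, a ribonucleotide reductase subunit (2.95-fold and 2.10-fold), and Ccne2, cyclin E2 (4.35-fold and 2.18-fold). Mitosis genes were called higher with smaller medians, 0.21 and 0.15, and 0 of 28 passed the rule. Gadd45a, a growth arrest gene, was 3.53-fold and 3.60-fold lower, and Cdkn1a, at 1744 against 2571 in GFP and 3303 in parental cells, did not pass. The unfolded protein and amino acid stress list was called lower (-1.44 and -0.42) with 4 of 27 genes past the rule: Vldlr (at least 13.8-fold and 5.33-fold), Herpud1 (6.44-fold and 6.16-fold), Chac1 (4.71-fold and 2.13-fold) and Phgdh (3.31-fold and 2.06-fold).

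MYC targets were looked at because the design sets MYC beside L122R. Ribosome biogenesis genes were called lower (-0.46 and -0.15), with 0 of 42 past the rule. Metabolism and growth targets were not called (-0.28 and -0.11), and Odc1, ornithine decarboxylase, was the only one of 45 genes past the rule, 2.10-fold above GFP and 2.60-fold above parental. Ncl, nucleolin, read 3244 against 3906 in GFP and 3244 in parental cells, and Cdk4 1225 against 1838 and 1429. Of the IGF, FGF and PI3K genes, 2 of 29 were higher and 3 lower with no list call (0.00 and -0.19), among them Igf2r (3.06-fold and 3.93-fold higher) and Igfbp4 (at least 4.69-fold and 5.71-fold lower). Fgfr4, a receptor of the myogenic lineage, was at the floor in GFP cells and on the arrays labelled L122R and MYC and read 171 in parental and 174 in wild-type MYOD1 cells.

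Unchanged simulated groups gave on average 42.8 higher and 39.9 lower genes and at most 65 and 60, below the observed 120 and 83. Against a single control the counts were 219 and 229 (GFP) or 183 and 197 (parental), a threshold per signal bin gave 241 and 41, and no floor gave 79 higher. Without normalization between arrays Odc1, Chac1 and Phgdh missed the rule, as did Ckm, Msc and Chrng at a floor at the 60th percentile. Over all comparisons, 83 calls of named genes were lost with a threshold per signal bin and 43 with no floor. The genes lost under those settings are not listed here.

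**Figure D3:**
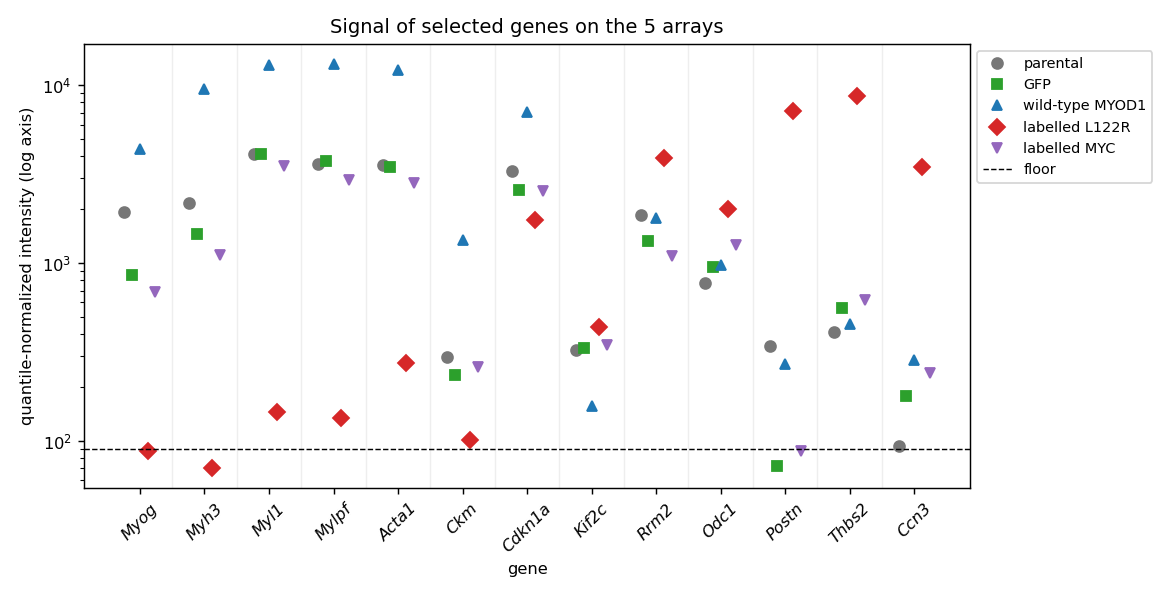
Quantile-normalized intensity of 13 named genes on the 5 arrays, on a log axis, with 1 point per array and the floor of 89.6 as a dashed line; points under the line are drawn at their own value and were raised to the floor for folds. Myog reads 4359 on the wild-type MYOD1 array and 87.8 on the array labelled L122R, and Postn reads 269 and 7187.

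The array labelled MYC was compared with both controls as the reference for a MYC response. It lay close to the GFP array, and 11 genes were higher and 1 lower by the rule. MYC targets in ribosome biogenesis were higher as a group by a small amount, with medians of 0.18 against GFP and 0.50 against parental, and sarcomere genes were lower by a small amount, with medians of -0.28 and -0.39. Mme, the membrane metalloprotease neprilysin, showed the largest increase, at least 8.46-fold against each control. Stmn2, a neuronal microtubule regulator, was the 1 lower gene, 2.18-fold below GFP and 3.72-fold below parental.

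The measured increases were Thbd, the anticoagulant receptor thrombomodulin (2.74-fold above GFP and 3.77-fold above parental), Ptn, the growth factor pleiotrophin (2.68-fold and 3.35-fold), Mfap2 (2.41-fold and 2.62-fold), Slpi (2.33-fold and 3.63-fold) and Gpnmb (2.25-fold and 3.54-fold). With a control at the floor, Akr1c14 was at least 3.27-fold and measured 2.95-fold higher, Fbln7 at least 3.14-fold against each, and Phex at least 2.90-fold and measured 2.56-fold. Col14a1 was 2.49-fold above GFP and at least 2.5-fold above parental, and Perp 2.14-fold and at least 2.75-fold.

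Of 42 ribosome biogenesis genes, 36 lay above GFP and 42 above parental, and 0 passed the rule of size. Ncl read 4844 against 3906 and 3244, 1.24-fold and 1.49-fold higher. Metabolism and growth targets were called higher with medians of 0.07 and 0.26, with 0 of 45 past the rule. In this list Odc1 was 1.33-fold and 1.65-fold higher, Cad 1.05-fold and 1.26-fold, and Cdk4 read 1836 against 1838 and 1429. Ribosomal protein genes were called higher (0.08 and 0.10, 0 of 38). The lists of S phase (0.04 and -0.37), mitosis (0.00 and -0.12), cell cycle exit (-0.01 and -0.34) and MYC-repressed genes (-0.02 and -0.22) were not called.

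Sarcomere genes had 0 of 39 past the rule, and 36 lay at or below each control. Myh3 was 1.31-fold below GFP and 1.97-fold below parental, Acta1 1.23-fold and 1.27-fold, and Myog 1.25-fold and 2.82-fold. Muscle membrane genes (-0.34 and -0.53, 0 of 22), calcium handling and energy genes (-0.08 and -0.27, 0 of 24), cholesterol synthesis genes (-0.23 and -0.22, 0 of 17), extracellular matrix genes (-0.08 and -0.56, 0 of 33), smooth muscle genes (-0.14 and -0.33, 0 of 15) and neural markers (-0.64 and -0.83, 1 of 6) were called lower. The calcium handling, matrix, smooth muscle and neural calls were each lost under at least 1 other setting of the floor or the normalization.

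Unchanged simulated groups gave on average 43.7 higher and 40.5 lower genes, more than the observed 11 and 1, while a threshold per signal bin gave 90 and 0. The counts were 22 and 4 against GFP alone and 108 and 139 against parental alone, so the comparison depends on which control is taken, and only 4 higher genes were left at a floor at the 60th percentile, with Stmn2 missing the rule when all probe sets of a gene were averaged.

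The array labelled L122R was then compared directly with the wild-type MYOD1 array. Most contractile genes were lower on the array labelled L122R. Mylpf was 97.0-fold lower, Myl1 88.4-fold, Actc1 67.6-fold and Acta1 44.1-fold, and Myh3 was at least 107-fold and Myog at least 48.6-fold lower. Mitosis and S phase genes were higher as groups, and among single genes the secreted proteins Postn (26.7-fold) and Thbs2 (19.1-fold) and the cyclin gene Ccnd2 (7.17-fold) were higher. Ccnd2 was not particular to the array labelled L122R. It read 2397 there, 1896 on the GFP array and 1683 on the array labelled MYC, against 334 on the wild-type array. In all, 229 genes were higher and 300 lower, against 127 and 133 between the controls.

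Of 39 sarcomere genes 34 were lower and 0 higher (median -3.02), and of 24 calcium handling and energy genes 15 were lower and 0 higher (-1.58), with Casq2 28.8-fold, Mb 24.7-fold and Ckm 13.5-fold lower. Myogenic transcription factors were called lower (-0.76), with 4 of 12 past 2-fold: Myog, Mef2c (4.30-fold), Mef2a (3.82-fold) and Myod1 (2.01-fold). Muscle membrane genes were called lower (-0.74, 7 of 22), including Chrng (at least 10.1-fold) and Ncam1 (3.73-fold). Further lower genes were Tnni2 (34.5-fold), Tnnt3 (32.0-fold), Tnnc2 (28.4-fold) and Tnnt2 (20.2-fold), all troponins, and Mybph (at least 70.3-fold).

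Mitosis genes were higher as a group (0.85, all 28 above 0, 5 past 2-fold), with Kif2c 2.77-fold, Cdk1, the mitotic kinase, 2.47-fold and Nusap1 2.10-fold higher. S phase genes were also higher (0.63, all 30 above 0, 6 past 2-fold), with Mcm3, part of the replicative helicase, 2.92-fold, Ccne2 2.62-fold and Rfc5 2.61-fold. Cell cycle exit genes were called lower (-0.30), with 4 of 13 past 2-fold: Gadd45a (4.22-fold), Cdkn1a (4.06-fold), Ccnd3 (2.57-fold) and Rb1 (2.05-fold). MYC targets were not called, neither in ribosome biogenesis (-0.12, 0 of 42) nor in metabolism and growth (0.11, 3 of 45 higher and 1 lower). In the latter Slc19a1, a folate carrier, was 3.0-fold and Odc1 2.05-fold higher, and Tfrc, the transferrin receptor, 2.59-fold lower.

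Slpi was 20.2-fold higher, Plagl1 14.5-fold, Ccn3 12.1-fold, Stc2 10.2-fold, Apcdd1 9.45-fold, Sprr1a 8.97-fold, Dtx1 8.72-fold and the fatty acid carrier Fabp5 8.54-fold. Sprr1a read 931 on the array labelled L122R but also 502 on the GFP array. Matrix genes were called lower (-0.39, with 4 of 33 higher and 9 lower), Bgn by 15.8-fold. Also called lower were the inhibitors of myogenesis (-0.44, with 2 of 20 higher and 2 lower), the stress response list (-0.43, 5 of 27 lower and 1 higher), IGF, FGF and PI3K genes (-0.20, 5 of 29 lower and 2 higher) and MYC-repressed genes (-0.14, 4 of 28 lower and 2 higher). Adipocyte markers were called higher (0.86, 1 of 7), with Pparg, the adipogenic nuclear receptor, at 2.25-fold. Without normalization between arrays 492 genes were higher and 196 lower, because the wild-type array was the dimmest. The adipocyte and MYC-repressed calls were lost at a floor at the 20th percentile, Myod1 missed 2-fold under 4 other settings and Rb1 under 3, and Kif2c missed it when all probe sets of a gene were averaged.

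**Figure D4:**
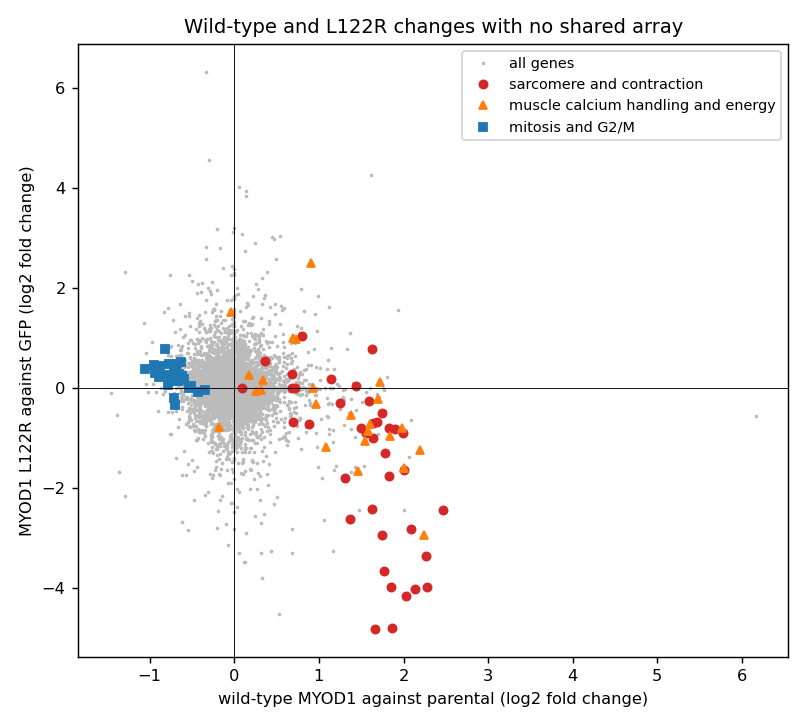
Log2 fold change of each gene on the wild-type MYOD1 array against parental (horizontal axis) and on the array labelled L122R against GFP (vertical axis), so that no array enters both axes, with 3 gene lists in colour. Sarcomere and calcium handling genes lie to the right and mostly below 0, mitosis genes lie to the left, and the correlation across all genes is -0.17.

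The array labelled L122R was also set directly against the array labelled MYC, with 229 genes higher and 215 lower. Sarcomere genes were again lower as a group, with Myl1 24.1-fold and Mylpf 21.7-fold lower, and Ccn2 was 25.6-fold, Ccn3 14.4-fold and Thbs2 14.0-fold higher, while the matrix list was not called (0.00, with 8 of 33 higher and 6 lower). The MYC target lists were lower on the array labelled L122R, as were the stress response and hypoxia lists that set the GFP array and the array labelled MYC apart from parental cells. The GFP array and the array labelled MYC were only 26 genes apart. Against GFP, L122R already had medians of -0.46 for ribosome biogenesis and -0.28 for metabolism and growth. The lower MYC targets therefore do not rest on the array labelled MYC alone. Car6 was 19.4-fold lower, and Chchd10, a mitochondrial protein, 13.4-fold lower.

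Sarcomere genes had 16 of 39 lower and 2 higher (median -0.58), the 2 being Ttn and Smyd1, named here after their values were seen. Ribosome biogenesis targets had a median of -0.65, with 4 of 42 lower: Nop58 (2.23-fold), Mybbp1a (2.16-fold), Wdr75 (2.03-fold) and Tsr1 (2.03-fold). Metabolism and growth targets had a median of -0.39, with 4 of 45 lower and 1 higher, including the amino acid transporter subunits Slc7a5 (2.59-fold) and Slc3a2 (2.53-fold). Stress response genes had a median of -1.37 and 17 of 27 lower, with Herpud1 6.47-fold, Trib3 4.06-fold and Ddit3 3.88-fold. Glycolysis and hypoxia genes had a median of -0.50 and 5 of 29 lower, with Ero1a 5.78-fold. S phase genes were higher (0.53, 6 of 30), with Rrm2 at 3.57-fold, and so were mitosis genes (0.28, 0 of 28), smooth muscle genes (0.42, 4 of 15) and inhibitors of myogenesis (0.26, 4 of 20), with Id2 at 5.96-fold. Calcium handling and energy genes (-0.26, 4 of 24 lower and 4 higher) and ribosomal protein genes (-0.18, 1 of 38) were called lower. The calcium handling call was lost at a floor at the 60th percentile, and Tsr1 and Wdr75 missed 2-fold under 3 other settings each.

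The overlap of the responses asked how far the array labelled L122R resembled the array labelled MYC or the wild-type MYOD1 array. L122R and the array labelled MYC shared 3 higher genes, Col14a1, Slpi and Thbd, and 1 lower gene, Stmn2, with 0 in opposite directions. Independent lists of those sizes would share 0.157 higher genes and 0.00986 lower ones, and unchanged arrays that share the controls shared 0.80 and 0.83 on average. The simulated lists, here and below, were of other sizes than the observed ones. They held on average 42.8 higher genes for L122R and 43.7 for the array labelled MYC, where 120 and 11 were observed. With parental as the only control 86 genes went in the same direction and 10 in opposite ones, with GFP 10 and 1, and 23 went in the same direction with a threshold per signal bin. L122R and wild-type MYOD1 shared 1 higher gene, Mymk, and 1 lower gene, Gsta4, while 30 genes were higher with wild-type MYOD1 and lower with L122R, against 0.976 for independent lists and 0.36 opposite genes in unchanged arrays. These 30 included Myog, Myh3, Acta1, Actc1 and Ckm. The number in the same direction depended on the rule, at 107 with GFP as the only control and 11 with parental. The 30 opposite genes met the rule against each control, so at least 30 stayed opposite with either control alone. With parental alone, opposite genes thus still outnumbered shared ones. A threshold per signal bin gave 27 in the same direction and 15 opposite. That threshold comes from the differences between the controls. Genes with both controls at the floor cannot be called lower, and a threshold drawn from them can be small, which favours shared higher calls. Wild-type MYOD1 and the array labelled MYC shared 0 genes in the main setting. Each control is a single array and could not be split further, so part of any excess may come from the shared controls.

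Of the 99 genes higher with wild-type MYOD1, 1 was higher, 30 lower and 68 neither on the array labelled L122R, with medians of -0.63 against GFP and -0.76 against parental. The number higher depended on the rule. Among genes higher with wild-type MYOD1 against a single control, L122R had 40 higher with GFP and 7 with parental. At least the same 30 were lower with either control alone. A threshold per signal bin, with the limit given above, gave 27 higher and 15 lower. On the array labelled MYC 0 of the 99 were higher and 0 lower, with medians of -0.21 and -0.37. The set formed with parental as the only control had 4 higher and 16 lower there. The set formed with GFP had 3 higher, and that with a threshold per signal bin 20 higher. The 11 genes higher on the array labelled MYC, which included Mme and Thbd, had a median difference of 0.00 between the array labelled L122R and the wild-type array, at the 47.0th percentile of random lists, with 5 of 11 above 0. With no floor the median was 0.29 and the set was called higher on the array labelled L122R. The matching set of lower genes held Stmn2 alone and was not tested.

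Fold changes over all 8422 genes, taken with 1 factor against GFP and the other against parental, correlated at -0.34 and -0.01 for L122R and the array labelled MYC (mean -0.18), at -0.17 and -0.36 for L122R and wild-type MYOD1 (mean -0.26) and at -0.73 and -0.18 for wild-type MYOD1 and the array labelled MYC (mean -0.45). With GFP as the shared control the values were 0.21, 0.26 and 0.13, where unchanged arrays gave 0.50 in each case. With parental as the shared control they were 0.38, -0.05 and 0.08, and unchanged arrays were not computed for that case. L122R thus correlated more with wild-type MYOD1 when GFP was shared and more with the array labelled MYC when parental was shared, so these correlations do not place it nearer to either. The covariances with GFP shared were 0.0198, 0.0628 and 0.0114, where unchanged arrays gave 0.0803, 0.0804 and 0.0804. Splitting the controls places their own difference on opposite sides of the 2 fold changes, which lowers the split values.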

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

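The tests of RNA degradation and of dilution by other cells were written down before their results were seen, except that the allowance for background in the dilution test was chosen only after they were seen. Gene lists stood out where the 2 forms of MYOD1 moved in opposite directions from both controls. The median log2 difference of L122R minus wild-type MYOD1 was -3.02 for sarcomere genes, -1.58 for calcium handling and energy genes and 0.85 for mitosis genes. With 1 array per form, these differences were not tested.

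The low level of muscle genes on the array labelled L122R was weighed further, because it went beyond a missing response and lay below the uninfected cells. Degraded RNA is argued against: the 3' to 5' signal ratio of the Actb control probe sets was 1.56 on that array, within the 1.49 to 1.71 of the other arrays, and that of Gapdh was 1.01. Dilution by cells that lack these transcripts is argued against as the whole cause. Over the 14 lower muscle genes measured on all sides, such dilution would give falls of a common size. The falls still spanned 7.02-fold against GFP and 6.29-fold against parental for any common background between 0 and the floor. Both spans run from Myl1 to Ncam1, and diluting cells that express Ncam1 would widen them. Against GFP, Tnnt2 kept a share of at least 0.247, close to the 0.250 of Ncam1. Against parental the next was Tnnc1, at 0.146 beside 0.225, so that span leaned on Ncam1. Diluting cells that express Tnnt2 or Tnnc1 would likewise raise the shares of those genes, which was not tested. Background that differs between probe sets was not allowed for. Of 97 genes of the 4 muscle lists 3 were higher than both controls, and of these Mymk and Sgca are muscle genes while Ckb is also expressed by other cells. An effect of the substituted protein, such as blocking the cells' own MYOD1, stays open as a hypothesis, and so does a difference in the density or differentiation state of the culture, which a single array cannot separate from it; replicate cultures matched for density, with binding of the cells' own MYOD1 mapped in the presence and absence of L122R, would decide between them.

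Signals also appeared in probe sets without exactly 1 named gene, which no comparison used. On the wild-type MYOD1 array 5 of 2246 such probe sets met the rule of size against both controls, on the array labelled L122R 12 and on the array labelled MYC 0.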

How the results depend on the processing

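No paired analysis was possible because each group holds 1 array, and leaving out a replicate was impossible for the same reason. No called list or named gene reversed its direction under the settings run. Losses of named genes' calls ranged from 0 at a floor at the 20th percentile to 83 with a threshold per signal bin; of 64 list calls, 8 were lost at a floor at the 60th percentile, 7 at the 20th and 0 with normexp correction. Signals near what appears to be unsubtracted background limit dim genes, and the cause of changes below was not tested unless stated. With GFP as the only control, which asks less by construction, genes higher and lower were 251 and 140 for wild-type MYOD1, 219 and 229 for L122R and 22 and 4 for the array labelled MYC. Of the genes higher with wild-type MYOD1, 40 were then higher with L122R and 3 with the array labelled MYC; L122R and wild type shared 107 genes in the same direction, and L122R and the array labelled MYC 10, with 1 opposite. Ribosome biogenesis for wild-type MYOD1 (-0.39) and metabolism targets for L122R (-0.28) were then called lower. With parental as the only control the counts were 10 lower for wild type, 183 and 197 for L122R and 108 and 139 for the array labelled MYC. Of the wild-type genes, 7 were then higher with L122R, and with the array labelled MYC 4 were higher and 16 lower; L122R shared 11 genes in the same direction with wild type and 86 with the array labelled MYC, with 10 opposite to the array labelled MYC. S phase genes then lay at -0.49 for wild type and -0.37 for the array labelled MYC. Without normalization between arrays (added after seeing the data), the median of all genes moved by 0.25 for GFP against parental, -0.39 for wild type, -0.13 for L122R and -0.12 for the array labelled MYC against GFP, and 0.23 for L122R against wild type; list values there are relative to these medians. By that shift, GFP against parental gave 285 higher and 70 lower, wild type 63 and 16, L122R against wild type 492 and 196, and the array labelled MYC 2 lower; the calcium handling call for the array labelled MYC was lost (-0.0769), as without cross-hybridising probe sets (-0.0767), where wild type had 1 lower gene. Median scaling gave 4 lower for wild type. A floor at the 60th percentile, with fewer genes tested, gave 4 higher for the array labelled MYC and 1 lower for wild type, and calcium handling calls were lost for L122R (0.00) and the array labelled MYC (-0.0194); fewer than 5 genes higher on the array labelled MYC were then left to rank in L122R. The mean of all probe sets gave 0 lower for the array labelled MYC, 1 lower for wild type and 2 genes shared by L122R and the array labelled MYC. With no floor, which shrinks folds by construction, counts were 6 higher and 0 lower for the array labelled MYC, 79 higher for L122R, 1 lower for wild type, 149 and 141 for L122R against the array labelled MYC, 137 higher for L122R against wild type and 82 lower for GFP, L122R and the array labelled MYC shared 2, and the genes higher on the array labelled MYC were called higher in L122R than in wild type (0.29). With a threshold per signal bin, counts were 182 and 0 for wild type, 241 and 41 for L122R and 90 and 0 for the array labelled MYC. Under this setting, genes with both controls at the floor cannot be called lower while their threshold can be small, which favours higher calls. Of the wild-type genes, 27 were then higher and 15 lower with L122R and 20 higher with the array labelled MYC; L122R shared 27 same and 15 opposite genes with wild type and 23 same with the array labelled MYC.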

Other observations

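The tests of infection, of a shared culture state or batch and of vector sequence below were chosen only after the pattern was seen, and genes named here were chosen after their values were seen.

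Beyond the comparisons, the arrays fell into pairs that differed over many lists, metabolic and stress genes among them. Relative to the mean of the parental and wild-type MYOD1 arrays, the unfolded protein and amino acid stress list had a median log2 difference of 0.81 on the GFP array and the array labelled MYC, with Atf3, Trib3, Asns, Psph and Sdf2l1 2-fold apart, and of -0.52 on the array labelled L122R. Glycolysis and hypoxia genes lay at 0.77 on the GFP array and the array labelled MYC, with Pfkl, Pgam1, Car9, Ndrg1 and Ero1a 2-fold apart, and at 0.04 on the array labelled L122R. Sarcomere genes lay at -1.06 on the GFP array and the array labelled MYC and at -2.03 on the array labelled L122R, but the reference holds the wild-type MYOD1 array, on which they rose, and GFP against parental alone gave -0.14. Inhibitors of myogenesis lay at -0.55 on the GFP array and the array labelled MYC and at -0.41 on the array labelled L122R. Other lists also separated the pairs, among them calcium handling (-0.83), myogenic transcription factors (-0.72), cell cycle exit (-0.66), muscle membrane (-0.55), matrix (-0.47) and ribosome biogenesis (0.44). The limit given for sarcomere genes holds for the muscle lists among these. Cholesterol synthesis (0.03) and p53 target genes (-0.02) did not separate the pairs, and neither list was called for wild-type MYOD1 or L122R. The interferon list was called for no factor.

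The split of GFP and the array labelled MYC from parental and wild-type MYOD1 covered 133 genes 2-fold apart between the pairs. Without normalization between arrays 166 genes were apart. Median intensity before normalization followed the same split, at 141 (GFP) and 131 (labelled MYC) against 112 (parental) and 108 (wild-type MYOD1). Brightness can thus add to the 166, so that count does not decide whether normalization shaped the split. For infection, the 260 genes 2-fold apart between GFP and parental were used, chosen without the other arrays: the array labelled MYC was nearer to GFP for 250 of them, L122R for 117 and wild-type MYOD1 for 15. Infection alone would place all 3 near GFP, but an effect of either MYOD1 form on the same genes cannot be told apart from it with 1 array each. A culture state or batch shared by 2 arrays stays open too: the 10 splits of 4 arrays that keep neither pair gave at most 5 genes and those that keep 1 pair 54 to 76, but any cause of the pairing would give this, and the labels name no batch and 2 vector systems, pcx4 and pBabe, without saying which construct used which.

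A probe set for Mycn read 12832, 6439, 8743 and 4215 on the GFP and wild-type MYOD1 arrays and the arrays labelled L122R and MYC and 78.0 on the parental array. A rise of the whole Mycn transcript is argued against, because the other 2 probe sets reached at most 69.4 on any array. Sequence of the retroviral vectors read by this probe set is a candidate explanation, since it was above the floor on all 4 infected arrays and below it on the parental array. The probe sequences and vector sequences were not used here, so the match itself was not tested, nor whether the vector system bears on either pattern.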
